A study of Pimephales promelas with 80 samples.

How the data were processed

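RNA was taken from single whole larvae of the fathead minnow (Pimephales promelas), a small freshwater fish used in toxicity testing. Larvae were kept for a day, unfed, in wells of a plate with 6PPD, an antioxidant added to tire rubber, or with 6PPD-quinone (6PPD-Q), the product it turns into by oxidation, in water with a little DMSO as solvent. The labels count the age of the larvae from hatching in one place and from fertilization in another, and they give more than 1 exposure volume, so neither is used here. The 80 libraries comprise 10 unexposed controls, 30 fish at 6 doses of 6PPD and 40 fish at 8 doses of 6PPD-Q, with 5 fish at each dose. Each library is a separate fish, and the larvae came from several crosses and were pooled before they were sorted to wells, per the labels. Of the plates, 77 libraries carry the label of plate C and 3 the label of plate A (control replicates 1 and 2, and replicate 1 at the highest 6PPD dose). Libraries were made from total RNA with a Lexogen SENSE mRNA kit, per the labels' protocols.

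The submitters' processing notes name bcl2fastq 2.20.0, Trim Galore 0.6.6, STAR 2.7.10a, SAMtools 1.13, HTSeq 0.13.5, MultiQC 1.12, FastQC and edgeR. The genome build, the gene annotation and the strand setting of the counting are not given in the sources used here. The authors deposited whole-number counts for 26150 genes in all 80 libraries, with 5 further lines that name no gene (reads outside any gene, ambiguous, of low quality, not aligned, or aligned to several places). These 5 lines stayed out of library sizes and tests. Reads outside any gene took 7.73% to 13.5% of a library's reads (median 10.5%), ambiguous reads 4.48% to 6.02%, and reads aligned to several places 5.68% to 9.76%. Genes in near-identical copies lose the last kind of read, so their levels are uncertain.

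The authors also deposited a table of log2 values for each chemical. In both, 2 to the power of the value minus 1 was proportional to the deposited count within each library, and the scaling differed by at most 5.31e-09% from edgeR's TMM factors, so the values are log2(TMM-normalized CPM + 1). The 6PPD table holds 40 libraries and 21219 genes. The 6PPD-Q table holds 48 libraries and 21464 genes and has no column for 2 exposed fish, replicate 3 at 0.277 mg/L and replicate 5 at 8.78 mg/L. Both fish are in the count table and were kept here. Of all 80 libraries, replicate 5 at 8.78 mg/L had the fewest genes detected (22110), the lowest share of reads in genes (74.3%) and the lowest TMM factor (0.884).

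Libraries held 16.2 to 36.6 M counts in genes (median 20.3 M) and detected 22110 to 23163 genes. The 10 most counted genes took 7.82% to 14.9% of a library. Between 2 libraries of a group, the chi-square per degree of freedom over genes was at least 13.0 in 185 pairs, so no pair agreed within sampling noise and none was counted as 1 sample. The biological coefficient of variation shared by all genes was 28.1%.

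Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test after estimateDisp, TMM factors), with Benjamini-Hochberg adjustment over the genes of each contrast and a threshold of 0.05. A gene past that threshold is called. All adjusted p-values of single genes come from this test unless another is named. The filter filterByExpr, by group, kept 21599 genes. Each dose was set against the 10 controls, and 6PPD-Q against 6PPD at 6 pairs of nearest doses, in 1 fit of all 80 libraries. A dose trend was fitted per chemical over its exposed fish and the controls, with the dose level (0 for controls, 1 for the lowest dose and so on) as a number. A difference of slopes was fitted as the interaction of chemical and log10 dose over the 60 fish of the 6 pairs. CPM values are counts per M of TMM-scaled library size, where M stands for 10 to the power of 6. Errors of log2 fold changes are standard errors derived from the F statistic, and intervals of differences of single genes are at 95% confidence. The per-gene tests were first tested on counts simulated from the real means and dispersions of 21599 genes with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. For 5 exposed against 10 control fish, 46.3% of 1.5-fold, 76.1% of 2-fold and 97.0% of 4-fold changes were recovered, with 5 false calls. For 5 fish against 5, the shares were 25.4%, 58.2% and 97.0%, also with 5 false calls.

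The gene identifiers of the files begin with FMg, and the files do not pair them with names. None of them matched the supplied RefSeq gene table (assembly fPimPro1.hap1.1, 64593 genes): 0 of 26150. The 38 gene lists written before the data were examined hold symbols, so they could not be matched and no list was tested. The rule fixed for naming genes took the 10 largest fold changes each way among called genes with a mean of at least 5 CPM over all fish and every exposed fish on the same side of the control mean, and it left unnamed a gene known by an identifier alone. By that rule no gene would be named. As an exception made after the values were seen, 4 identifiers are printed, the first gene each way by the rule's ranking at the highest dose of each chemical. The genes ranked second each way at the highest 6PPD dose are described without identifiers, also a choice made after the values were seen.

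The response score was also added after the calls were seen. Genes for it were chosen by the same test from replicates 1 to 3 at the highest 6PPD dose against the 5 odd-numbered controls, 1699 that were higher and 1307 that were lower. The score of a fish is its mean log2 CPM (prior count 2) over the first set minus that over the second, relative to the mean of the 5 even-numbered controls. Fish used to choose the genes were not scored. Scores were compared by two-sided exact permutation tests.

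The alternatives fixed at the same stage as the gene lists were DESeq2 1.42.0 (Wald test), RLE size factors, no low-count filter, fits of only the libraries of the groups compared, leaving out the plate A libraries, a block for replicate number, log10 dose over exposed fish only, limma 3.58.1 on the authors' log2 values, and leaving out each fish in turn. Added later were the share of reads outside genes as a covariate, leaving out the 2 fish absent from the authors' 6PPD-Q table, and leaving out each dose from the trends. On the simulated counts of 5 exposed and 10 control fish, DESeq2 in a fit of these 15 libraries made 19 false calls among 164. edgeR made 7 among 132 in a fit of the same 15 libraries and 5 among 151 in the fit of 80, and limma made 5 among 130. The DESeq2 counts reported for doses and pairs come from a fit of all 80 libraries. DESeq2 was not simulated in that setting, so its rate of false calls there is not known.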

Results

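Whole-body transcriptomes of 80 single fathead minnow larvae were sequenced after a day without food in water with 6PPD, with its quinone 6PPD-Q, or with neither. The series asks whether either chemical alters the larval transcriptome and whether the response says anything about how 6PPD-Q acts and why fish species differ in sensitivity to it. Nominal doses of 6PPD were 0.00848, 0.0268, 0.0848, 0.268, 0.848 and 2.68 mg/L. Those of 6PPD-Q were 0.00277, 0.00878, 0.0277, 0.0878, 0.277, 0.878, 2.77 and 8.78 mg/L. There were 5 fish per dose and 10 controls common to both chemicals. Control libraries held 16.2 to 21.7 M counts in genes. The 5 libraries of the highest 6PPD dose held 16.8 to 26.1 M and those of the highest 6PPD-Q dose 17.2 to 20.8 M.

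The first question was at which doses 6PPD altered gene expression. Larvae at 2.68 mg/L had a broadly altered transcriptome: 2674 genes were higher and 2100 lower than in controls, 4774 of 21599 tested. The median size of change of the called genes was 0.65 on the log2 scale, and 574 of them rose and 541 fell by more than 1. The genes that rose took 10.5% ± 0.28 of all counts in controls (SD, n = 10) and 17.1% ± 1.96 at this dose (n = 5), and those that fell took 11.4% ± 0.26 and 7.25% ± 0.94. These shares describe genes chosen in the same fish, so their direction is fixed by the choice. The median log2 change over all tested genes was -0.01. Without the plate A libraries, which leaves 4 exposed and 8 control fish of plate C, 2958 genes were called, 2864 of them among the 4774. Leaving out the plate A fish of this dose alone (replicate 1) gave 3162.

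At the next dose, 0.848 mg/L, 162 genes were higher and 28 lower than in controls, 190 in all, with a median size of change of 0.80 on the log2 scale. Of these, 155 also rose and 22 also fell at 2.68 mg/L, and none went the other way. With separate controls (odd-numbered and even-numbered) for the doses, 114 or 118 genes were called the same way at both. Independent lists of those sizes share 10.7 or 10.5 genes that were higher and 1.53 or 0.794 that were lower. Of the called genes, 85.3% were higher than in controls at 0.848 mg/L and 56% at 2.68 mg/L, and the difference between these shares was not tested.

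Below 0.848 mg/L, 6PPD gave next to no called genes. At 0.00848 mg/L, 2 genes were called, 1 each way, and leaving out replicate 1 of that dose gave 0, with 739 at an unadjusted p under 0.05 over all fish, 3 called by DESeq2 and 0 by limma. Leaving out any 1 of control replicates 2, 3, 4, 5, 9 and 10 or of replicates 3, 4 and 5 of that dose gave 1. At 0.0268, 0.0848 and 0.268 mg/L, edgeR called 0 genes, with 358, 989 and 760 genes at an unadjusted p under 0.05, DESeq2 called 2, 3 and 3 and limma 0 at each. Simulated 4-fold changes were nearly all found at this group size, against 46.3% of 1.5-fold changes, so changes of about 1.5-fold would often have been missed with 5 fish. That simulation changed many genes at once. Where few genes change, the adjustment over genes is stricter, so larger changes may have been missed at these doses as well.

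**Figure D1:**
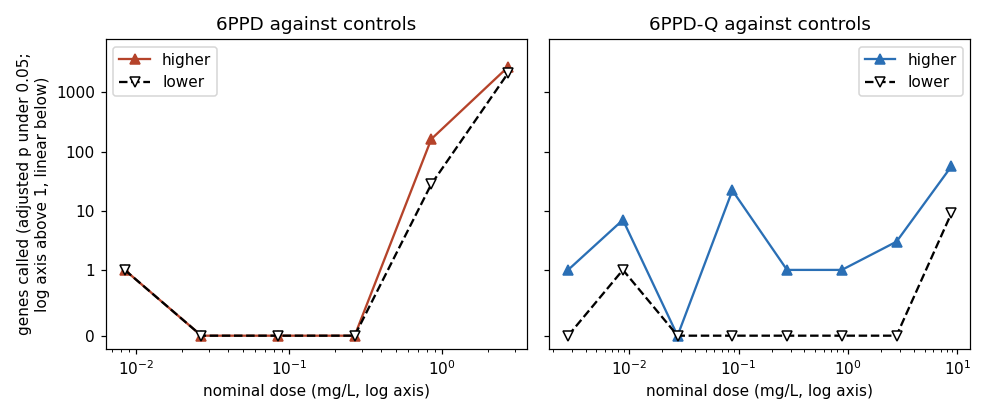
Genes called higher (filled triangles) and lower (open triangles) than in the 10 controls at each nominal dose (mg/L, log axis) of 6PPD and 6PPD-Q, 5 fish per dose. The vertical axis is logarithmic above 1. Calls for 6PPD went from 0 at 0.268 mg/L to 190 at 0.848 and 4774 at 2.68 mg/L, while 6PPD-Q reached 65 at 8.78 mg/L.

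FMg014186 had the largest fitted rise at 2.68 mg/L of 6PPD among the genes that met the naming rule. It stood at 3.49 ± 1.94 CPM in controls (SD, n = 10), 5.21 ± 1.59 at 0.268 mg/L, 79.8 ± 51.0 at 0.848 mg/L and 278 ± 77.5 at 2.68 mg/L (n = 5 each). Its log2 fold change was 4.51 ± 0.44 (SE, adjusted p = 3.61e-12) at 0.848 mg/L and 6.31 ± 0.46 (adjusted p = 2.32e-18) at 2.68 mg/L. The gene ranked second rose from 7.13 ± 1.83 CPM in controls to 189 ± 97.2 at 0.848 mg/L and 365 ± 77.9 at 2.68 mg/L, a log2 fold change of 5.67 ± 0.30 (adjusted p = 1.8e-25). In both genes every fish at 0.848 and 2.68 mg/L lay above the highest control. That control was at 7.54 CPM for FMg014186.

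FMg025091 ranked first, by the naming rule, among the genes that fell at 2.68 mg/L of 6PPD, from a mean of 7.35 CPM in controls (range 0 to 30.2, n = 10) to 0.07 ± 0.05 (SD, n = 5) (adjusted p = 0.0306). Its fitted log2 fold change of -6.61 ± 2.32 rests on 0 to 2 counts per exposed fish and is no bound on the size of the fall. Controls ranged from 0 to 541 counts, and 34 of all 80 fish had at most 3 counts. The call was lost without any 1 of the 5 exposed fish (adjusted p = 0.072, 0.0626, 0.0571, 0.0527 and 0.0688 without replicates 1 to 5) and without control replicate 5 (adjusted p = 0.0555), and the adjusted p reached 0.199 with limma. FMg025091 was as low at 0.878 mg/L of 6PPD-Q, at 0.07 ± 0.06 CPM (SD, n = 5), and did not pass the test there. The gene ranked second fell more evenly. It went from 16.7 ± 11.8 CPM in controls, with a lowest fish at 5.73, to 0.47 ± 0.44 at 2.68 mg/L (log2 fold change -5.19 ± 0.85, adjusted p = 1.71e-06). At 0.848 mg/L that gene was at 6.24 ± 4.79 CPM and did not pass the test (adjusted p = 0.496).

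**Figure D2:**
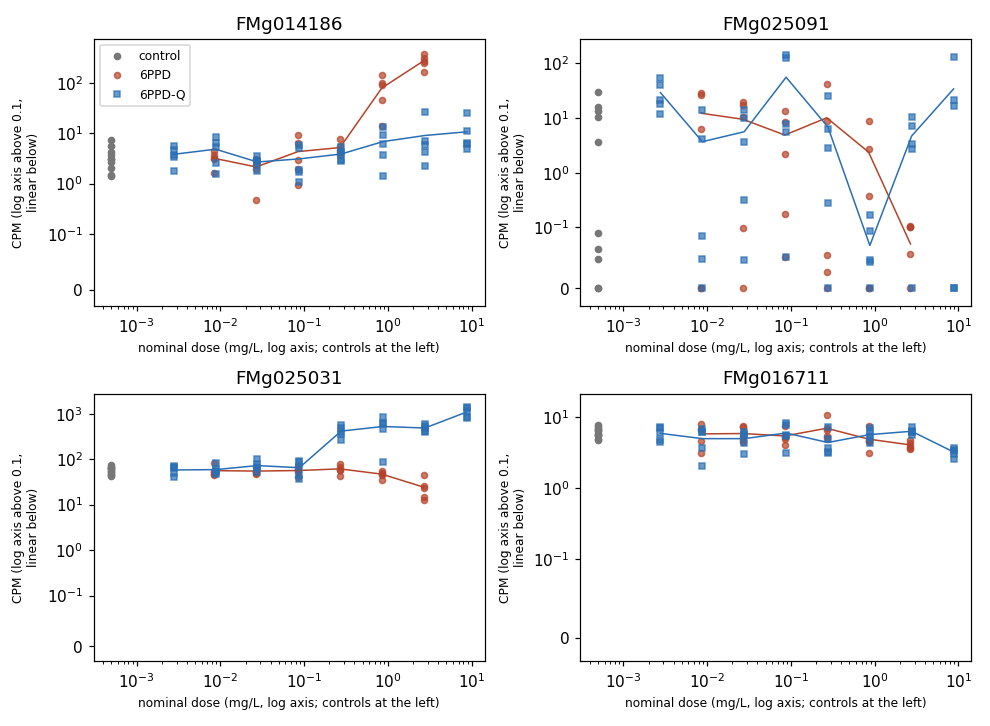
CPM (vertical axis, logarithmic above 0.1) of the 4 genes named here in each fish against nominal dose (mg/L, log axis), with controls at the left, 6PPD as circles, 6PPD-Q as squares, and lines through the means of 5 fish. FMg014186 climbed with 6PPD from 0.848 mg/L on, FMg025031 was higher than in controls with 6PPD-Q from 0.277 mg/L on, and FMg025091 was near 0 in some fish of nearly every group.

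The second question was whether 6PPD-Q altered gene expression. The clearest change was in a single gene, FMg025031, which was called higher at the 4 doses from 0.277 mg/L up. It stood at 57.2 ± 10.7 CPM in controls (SD, n = 10) and 64.8 ± 24.6 at 0.0878 mg/L. It reached 413 ± 118 CPM at 0.277, 523 ± 280 at 0.878, 483 ± 82.7 at 2.77 and 1089 ± 266 at 8.78 mg/L (n = 5 each). All 5 fish at each of these 4 doses were above the highest control, at 74.9 CPM. The lowest of them, replicate 5 at 0.878 mg/L, was near it at 86.6 CPM. At 0.00878, 0.0277 and 0.0878 mg/L, where the gene was not called, 1, 2 and 2 of 5 fish were above that control as well. The log2 fold change was 2.85 ± 0.23 (SE, adjusted p = 9.26e-15) at 0.277 mg/L and 4.25 ± 0.24 (adjusted p = 3.33e-23) at 8.78 mg/L. With the parent compound the same gene did not rise. It was at 24.2 ± 12.7 CPM at 2.68 mg/L of 6PPD, lower than in controls (log2 fold change -1.24 ± 0.26, adjusted p = 0.000138).

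At 8.78 mg/L of 6PPD-Q, 56 genes were higher and 9 lower than in controls. Of those that rose and met the naming rule, the gene with the second largest fold change was also the one ranked second among the genes that rose at 2.68 mg/L of 6PPD. It stood at a mean of 44.0 CPM (range 16.8 to 63.3, n = 5) at 8.78 mg/L (log2 fold change 2.62 ± 0.28, adjusted p = 1.02e-09). FMg014186 was at 10.7 ± 8.33 CPM and did not pass the test at this dose (log2 fold change 1.62 ± 0.44, adjusted p = 0.0742). Among the genes that fell and met the naming rule, FMg016711 had the largest change, from 6.12 ± 0.97 CPM in controls to 3.23 ± 0.43, by 0.92 ± 0.22 on the log2 scale (adjusted p = 0.0376). It also was lower at 2.68 mg/L of 6PPD (log2 fold change -0.59 ± 0.22, adjusted p = 0.0395). The call at 8.78 mg/L was lost without exposed replicate 1, 3 or 5 (adjusted p = 0.177, 0.106 and 0.0977) or control replicate 2, 5, 6 or 8 (adjusted p = 0.0532, 0.0542, 0.0662 and 0.0577), and the adjusted p was at most 0.221 over all alternatives. The count of 65 depended on single fish: it was 27 without replicate 5, 40 without replicate 1, 294 without replicate 2 and 268 without replicate 4. DESeq2 called 148 genes, and limma 15 on the authors' log2 values, which lack replicate 5.

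At lower doses of 6PPD-Q few genes were called. From the lowest dose up to 2.77 mg/L the counts were 1, 8, 0, 22, 1, 1 and 3. At 0.0277 mg/L edgeR called 0 genes, with 968 at an unadjusted p under 0.05, DESeq2 called 3 and limma 0. The single genes called at 0.277 and 0.878 mg/L, and 1 of the 3 called at 2.77 mg/L, were FMg025031. The 22 genes at 0.0878 mg/L were all higher. Without replicate 5 of that dose 1 of them was called, without replicate 4 the count was 14, without replicate 1 it was 77, and limma called 2. The 8 genes at 0.00878 mg/L became 216 without replicate 2 of that dose, 24 without replicate 1, 3 without replicate 4 and 0 without replicate 3 or 5, and 0 or 1 without any 1 of control replicates 1, 2, 3, 5, 6, 9 and 10. The 1 gene at 0.00277 mg/L was lost without replicate 4 or 5 of that dose or without control replicate 2, 3, 4, 7 or 10, and 2 genes were called without control replicate 9. In fits of the controls and 1 dose alone, edgeR called 0 genes at 0.00277, 0.00878 and 0.0878 mg/L. Over all fish 674, 2135 and 2232 genes were at an unadjusted p under 0.05 at these doses, and DESeq2 called 6, 35 and 25. At 0.878 mg/L, 2 genes were called without replicate 1 of that dose or control replicate 8 or 9, and at 2.77 mg/L, 5 without replicate 5. Over the 8 doses, 94 genes were called at least once, 5 were higher at 2 doses or more, and 0 were lower at 2 or more.

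Changes that went on with dose were looked for with a slope over the dose levels of each chemical. For 6PPD, 1867 genes rose and 1016 fell with dose, 2883 in all, and 2642 of them were also called, in the same direction, at 2.68 mg/L. Without the fish at 2.68 mg/L, 114 genes had a trend, 109 of them among the 2883. Without the plate A libraries the count was 1717, and without replicate 1 at 2.68 mg/L, the plate A fish of that dose, it was 1885. For 6PPD-Q, 30 genes rose and 1 fell with dose. FMg025031 rose by 0.55 ± 0.04 on the log2 scale per dose level (SE, adjusted p = 1.01e-15), and FMg014186 by 0.19 ± 0.04 (adjusted p = 0.0451). Without the fish at 8.78 mg/L, 5 genes had a 6PPD-Q trend, 3 of them among the 31.

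The 2 chemicals differ in structure, the quinone being the oxidized form of the parent. They were compared directly at 6 pairs of nominal doses in which 6PPD-Q was 3.31% or 3.57% higher in mg/L. Doses were matched by mass, and molar doses were not compared. At 2.77 against 2.68 mg/L, 1879 genes were higher and 2386 lower with 6PPD-Q than with 6PPD, 4265 in all. At 0.878 against 0.848 mg/L, 11 were higher and 71 lower. FMg014186 was at 9.07 CPM with 6PPD-Q and 278 with 6PPD at the highest pair, a log2 difference of -4.93 (95% interval -6.09 to -3.77, adjusted p = 5.57e-10). FMg025031 went the other way, with 483 against 24.2 CPM at the highest pair (log2 difference 4.32, 95% interval 3.69 to 4.96, adjusted p = 7.28e-18). At 0.277 against 0.268 mg/L, FMg025031 was the single gene that differed (2 genes without 6PPD replicate 3), with 413 against 61.1 CPM and a log2 difference of 2.76 (95% interval 2.17 to 3.35, adjusted p = 1.5e-09). At 0.0878 against 0.0848 mg/L its difference was 0.21 (95% interval -0.35 to 0.76, adjusted p = 0.76).

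At the 3 lowest pairs 2, 0 and 27 genes differed, and in fits of the 2 groups alone edgeR called 0 at each. Over all fish 1680, 358 and 3238 genes were at an unadjusted p under 0.05, and DESeq2 called 9, 0 and 102. The 2 became 94 without replicate 2 of 6PPD-Q and 0 or 4 without its other fish, and 1 or 0 without 6PPD replicate 2, 3, 4 or 5. Each of the 10 fish of the third pair moved the 27 by over 1.5 times: without 6PPD-Q replicates 1 to 5 in turn it was 482, 12, 70, 11 and 1, and without 6PPD replicates 1 to 5 it was 4, 3, 4, 9 and 5. The slope on log10 dose differed between the chemicals for 1084 genes, with a higher slope for 6PPD-Q in 306 and a lower one in 778. The sign of this difference does not say with which chemical a gene rose or fell. The slope of FMg014186 was lower for 6PPD-Q, with a difference of -2.34 ± 0.32 on the log2 scale per unit of log10 dose (adjusted p = 1.54e-06) and that of FMg025031 was higher by 1.88 ± 0.21 (adjusted p = 2.22e-08). Without the highest pair of doses 8 genes differed in slope, and without replicate 1 at 2.68 mg/L of 6PPD, the plate A fish among these 60, the count was 640.

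**Figure D3:**
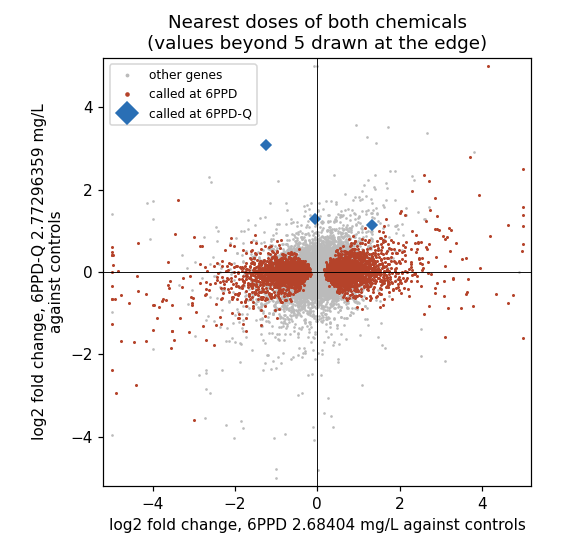
Log2 fold change against controls of each of 21599 tested genes at 2.68 mg/L of 6PPD (horizontal) and at 2.77 mg/L of 6PPD-Q (vertical), with values beyond 5 drawn at the edge. The 4774 genes called at 6PPD are in red and the 3 called at 6PPD-Q are blue diamonds, and the red genes lie along the horizontal axis.

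Of the 3 genes called at 2.77 mg/L of 6PPD-Q, 1 was called in the same direction at 2.68 mg/L of 6PPD and 1, FMg025031, in the opposite direction. Across genes, which are not independent replicates, the fold changes of the 2 groups correlated at r = 0.23 (covariance 0.0414). Unchanged groups simulated 100 times, with controls common to both, gave r = 0.33 on average, a covariance of 0.0265 (SD 0.00114 over simulations) and 0 shared calls. The r values cannot be compared, because the simulated groups held no changed genes while 4774 were called at 2.68 mg/L of 6PPD. The lower observed r is therefore not read as less similarity than in unchanged groups. The observed covariance was higher by 0.0149. That SD is between simulations, not between real fish, and the excess was not tested. Independent lists of these sizes share 0.371 genes that were higher. With odd-numbered controls for one chemical and even-numbered controls for the other, r was 0.083 or 0.0884 and 1 or 0 genes were shared.

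The genes of the 6PPD response were also read as a score in fish that had no part in choosing them, a measure added after the calls were seen. Genes were chosen in 3 fish at 2.68 mg/L and 5 controls and read in the other fish. The score was 1.35 ± 0.34 (SD, n = 2) in the other fish at 2.68 mg/L and 0.54 ± 0.17 (n = 5) at 0.848 mg/L of 6PPD, with 5 of 5 fish above the highest of 5 held-out controls at 0.0828. At 0.848 mg/L the exact permutation p was 0.00794, the smallest the test can give, and 0.111 after adjustment over 14 doses. At the 4 lower doses the mean score lay between 0.0198 and 0.133. At 8.78 mg/L of 6PPD-Q the score was 0.24 ± 0.16 (n = 5), with 4 of 5 fish above the highest control (exact permutation p = 0.0159, adjusted p = 0.111). At 2.77 mg/L of 6PPD-Q it was 0.05 ± 0.09. At 0.0277 and 0.0878 mg/L of 6PPD-Q it was 0.10 ± 0.18 and 0.15 ± 0.18, each with 3 of 5 fish above the highest control (exact permutation p = 0.31 and 0.111, adjusted p = 0.361 and 0.311). At 2.68 mg/L of 6PPD, 2 fish against 5 controls gave an exact permutation p of 0.0476, the smallest that test can give, and 0.194 after adjustment. The score was lower at 0.878 mg/L of 6PPD-Q than at 0.848 mg/L of 6PPD, with a difference of -0.492 (exact permutation p = 0.00794, adjusted p = 0.0476 over 6 pairs). At the highest pair the difference was -1.3 (exact permutation p = 0.0476, adjusted p = 0.143), and at the 4 lower pairs, in order of rising dose, it was -0.0987, 0.0773, 0.106 and 0.0271, with adjusted p of 0.254 or more.

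**Figure D4:**
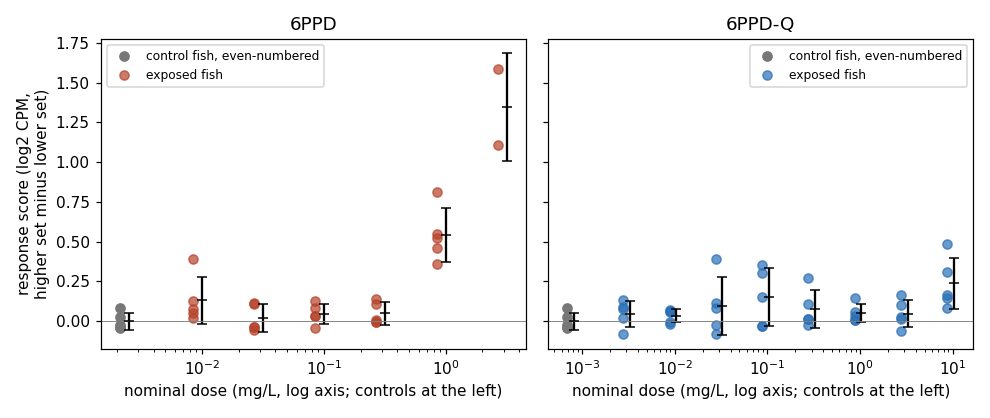
Response score of each fish (log2 CPM, mean of 1699 genes minus mean of 1307 genes, relative to the even-numbered controls) against nominal dose (mg/L, log axis) for 6PPD and 6PPD-Q, with the mean and SD beside each group. Fish used to choose the genes are not drawn, so 2 fish remain at 2.68 mg/L of 6PPD. The 5 fish at 0.848 mg/L of 6PPD lie between 0.361 and 0.813, and the fish at 8.78 mg/L of 6PPD-Q between 0.0816 and 0.485.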

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

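The test for a response shared with 6PPD, the test on neighbouring identifiers, the covariate for reads outside genes and the response score were chosen after the results they bear on were seen.

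Differences between the chemicals were found by a test of the difference itself. At nearest doses 2, 27, 1, 82 and 4265 genes differed, in order of rising dose with the pair that gave 0 left out, and the slope on dose differed for 1084 genes. The 2 and the 27 became 0 in fits of the compared groups alone, and few genes differed in slope without the highest pair of doses. In 13 of 134 groups of values a single fish stood far from the others of its group. Chance gives about 1 in 20 if values are normally distributed. Most flags were CPM values, not on a log scale, of genes picked for large changes, so an excess over chance is not shown. Among library totals the flagged fish were replicate 4 at 0.268 mg/L of 6PPD with 36.6 M counts and replicate 1 at 0.00277 mg/L of 6PPD-Q with 27.4 M. Replicate 3 at 0.277 mg/L of 6PPD-Q, a fish without a column in the authors' log2 table, had 12.6% of its reads outside genes. The response score of replicate 1 at 0.00848 mg/L of 6PPD was 0.389, and the CPM of FMg025031 in that fish was 81.6. FMg014186 was at 26.1 CPM in replicate 1 at 2.77 mg/L of 6PPD-Q, where the gene ranked second among those that rose with 6PPD was at 35.3 CPM. That second gene was at 24.3 CPM in replicate 5 at 0.878 mg/L of 6PPD-Q. The gene ranked second among those that fell was at 84.9 CPM in replicate 3 at 0.0878 mg/L of 6PPD-Q. FMg025091 was at 30.2 CPM in control replicate 5, 41.6 in replicate 5 at 0.268 mg/L of 6PPD, 24.7 in replicate 5 at 0.277 mg/L of 6PPD-Q and 131.6 in replicate 1 at 8.78 mg/L of 6PPD-Q.

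The first pattern weighed is the set of 22 genes called higher at 0.0878 mg/L of 6PPD-Q. A single fish may carry these calls, since 1 of the 22 was called without replicate 5. A higher share of reads outside genes in these fish stays open, as 15 of the 22 were called with that share as a covariate. An effect of 6PPD-Q that goes on with dose also stays open. Between 8.78 mg/L of 6PPD-Q and 0.0268 mg/L of 6PPD the median log2 difference of the set was 0.66. At its own dose, against controls, the median change of the set was 1.84. The 95% interval of the 0.66, 0.28 to 1.05, came from resampling the 22 genes and does not measure spread between fish. Of the 22, 0 were among the 31 genes with a 6PPD-Q dose trend, and 0 were called at 0.277, 0.878 or 2.77 mg/L of 6PPD-Q. At 8.78 mg/L 3 of them were called higher.

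The second pattern is the set of 65 genes called at 8.78 mg/L of 6PPD-Q. Replicate 5, the fish without a column in the authors' table, may carry many of these calls, since 20 of the 65 were called without it. A higher share of reads outside genes cannot be told apart, with 43 of 65 called when it was a covariate. A response that 6PPD gives as well is a candidate explanation for part of the set: with separate controls at least 12 genes were called the same way here and at 0.848 mg/L of 6PPD, where independent lists of those sizes share 0.0844 genes that were higher.

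The third pattern is a set of 77 genes, FMg025091 among them, with at most 3 counts in at least 8 fish and at least 5 CPM in at least 8 others. Exposure was not found as the source over the set, as groups held a median of 18% of the variance and the 95th percentile of shuffled groups was 19%. A median so near that limit does not exclude exposure, least of all for single genes. Of the 77 genes, 8 were called at a dose, 7 of them at 2.68 mg/L of 6PPD, where 4774 of 21599 tested genes were called. Library depth was not found as the source either, and is not excluded. The median absolute rank correlation was 0.0847, against a 95th percentile of 0.0968 in shuffled totals. Inherited differences between fish in stretches of the genome could be behind it: 2 of 4 pairs with identifier numbers at most 3 apart had r above 0.5, and 1000 shuffles gave at most 1. That test rests on 4 pairs and on the assumption that nearby numbers are neighbours in the genome.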

How the results depend on the processing

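The covariate for reads outside genes, leaving out the 2 fish absent from the authors' 6PPD-Q table and leaving out doses were chosen after seeing the data. Single genes were refitted at 1 dose each, 8.78 mg/L of 6PPD-Q for FMg025031 and FMg016711 and 2.68 mg/L of 6PPD for the others, and their calls at other doses and in trends were not refitted. At that dose FMg014186, FMg025031 and both second-ranked genes kept their direction and their call in each of 24 refits, and FMg016711 and FMg025091 kept their direction and lost the call in 11 and 8. Causes were not tested unless stated. With RLE factors each of 25 results stayed within 1.5 times. The alternatives for gene lists could not run, since no list matched. With 5 fish per dose, 46.3% of simulated 1.5-fold changes were called, which limits what can be said of small changes.

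DESeq2 called 2, 3 and 3 genes at 0.0268, 0.0848 and 0.268 mg/L of 6PPD (0 in edgeR). For 6PPD-Q it called 6, 35, 3, 3, 4, 12 and 148 at 0.00277, 0.00878, 0.0277, 0.277, 0.878, 2.77 and 8.78 mg/L, and 9, 102, 3 and 132 at the nearest-dose pairs with 6PPD-Q at 0.00878, 0.0878, 0.277 and 0.878 mg/L. Without a filter 5 genes were called at 0.00878 mg/L of 6PPD-Q, 1 differed at the lowest pair and 51 had a 6PPD-Q trend. In fits of the 2 groups compared, 0 genes were called at 0.00277, 0.00878 and 0.0878 mg/L of 6PPD-Q, 7 at 2.77 mg/L, and 0 differed at the pairs with 6PPD-Q at 0.00878 and 0.0878 mg/L. Without the plate A fish, 1 and 2958 genes were called at 0.00848 and 2.68 mg/L of 6PPD, 0 at 0.00277 and 0.00878 mg/L of 6PPD-Q, 1717 had a 6PPD trend and 640 differed in slope. limma called 0, 3, 2, 9 and 15 genes at 0.00277, 0.00878, 0.0878, 2.77 and 8.78 mg/L of 6PPD-Q and 0 at 0.00848 mg/L of 6PPD. With the covariate, 0 genes were called at 0.00848 mg/L of 6PPD, 76 at 0.00878 mg/L of 6PPD-Q, and 5 differed at the pair with 6PPD-Q at 0.0878 mg/L. Without the 2 absent fish 13, 6 and 27 genes were called at 0.00878, 2.77 and 8.78 mg/L of 6PPD-Q. Without its highest dose 114 genes had a 6PPD trend and 5 a 6PPD-Q trend, and without the highest pair 8 differed in slope. With split controls the correlation of the chemicals was 0.083 or 0.0884, and 0 genes were shared one way round.

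With replicate number as a block, 0, 106 and 3139 genes were called at 0.00848, 0.848 and 2.68 mg/L of 6PPD, 0, 1, 0, 2, 1 and 21 at 0.00277, 0.00878, 0.0878, 0.878, 2.77 and 8.78 mg/L of 6PPD-Q, and 5 differed at the pair with 6PPD-Q at 0.0878 mg/L. Exposed fish were not seen to pair with same-numbered controls. Such pairs correlated at -0.271 to 0.248, and 0 of 14 groups had every pair above 0.1. Of 70 exposed fish, 10 correlated best with the control of their own number. Exposed fish of different doses were not compared with each other, so something they share by replicate number is not excluded. Replicate 5 of every 6PPD-Q dose, for example, lay in plate row H.

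Leaving out 1 fish at a time moved 64 of 420 counts by over 1.5 times. The counts for 6PPD ranged from 0 to 3, 0 to 0, 0 to 0, 0 to 0, 132 to 187 and 3162 to 4912 with rising dose. Those for 6PPD-Q ranged from 0 to 2, 0 to 216, 0 to 0, 1 to 77, 1 to 1, 1 to 2, 2 to 5 and 27 to 294. Those for the pairs ranged from 0 to 94, 0 to 0, 1 to 482, 1 to 2, 57 to 98 and 2958 to 4585. The 6PPD trend ranged from 1885 to 3149, the 6PPD-Q trend from 21 to 40, and the difference of slopes from 640 to 1474.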

Other observations

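Every test in this part on principal components, read shares and separate controls was chosen after the data were seen, while the counts of other splits were planned.

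Genes called at 8.78 mg/L of 6PPD-Q moved in part as they did with 6PPD. Of the 65 genes, 38 were called the same way and 2 the opposite way at 2.68 mg/L of 6PPD. With separate controls for the 2 doses, 16 or 15 genes were called the same way, where independent lists share 2.02 or 1.6 genes that were higher.

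The first principal component of the 80 fish took 8.83% of the variance and went with the share of reads outside genes (Pearson r = 0.944, Spearman rho = 0.938, permutation p = 1e-05 for each, the smallest the permutations can give, adjusted p = 4e-05 over 4 components). Without the 2 farthest fish r was 0.938, within groups it was 0.939, and among plate C fish 0.947. Plate A holds 3 fish, too few for a correlation of its own. The 8 fish in plate column 12, all exposed to 6PPD-Q, had 12.2% ± 0.688 of reads outside genes. Plate rows differed too: fish of row E, of both chemicals, had 10.5% to 13.5%, and those of row G, also of both, 7.73% to 11.5%. Whether plate position or exposure lies behind the share in column 12 was not tested. The third component took 6.21% of the variance, and the 5 fish at 2.68 mg/L of 6PPD lay at 45.4 to 88.9 on it, above all fish of the other groups.

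Fish were split in other ways into groups of the same sizes, 100 splits for each comparison with the real one among them. These fits held the compared fish alone, so the real counts of the dose comparisons differ from those of the fit of all 80. The real split is 1 of the 100, so no comparison could give less than 1 in 100. These shares were not adjusted over the comparisons, so chance is called unlikely, not excluded, where only the real split reached the real count. For 6PPD, chance is unlikely at 2.68 mg/L (1 split of 100 as large, 5204 genes, highest other 424) and at 0.848 mg/L (1 split, 266 genes, highest other 14). At 0.00848 mg/L 2 splits reached the real count of 3 genes, the highest other being 3 as well, and chance is left open there, since 0 genes were called without replicate 1 of that dose or by limma. At 0.0268, 0.0848 and 0.268 mg/L the real count was 0, which all 100 splits reach by construction, so the splits say nothing about chance (highest others 1, 87 and 4). For 6PPD-Q, chance is unlikely at 2.77 mg/L (1 split, 7 genes, highest other 2) and 8.78 mg/L (1 split, 55 genes, highest other 10). This holds for the counts of these fits, which include 2 of the 3 genes called at 2.77 mg/L in the fit of all 80 fish and 36 of the 65 at 8.78 mg/L. At 0.00277, 0.00878, 0.0277 and 0.0878 mg/L the real count in these fits was 0, so the 100 splits again say nothing, and the genes called there in the fit of all 80 fish were not put to this test (highest others 119, 2, 3 and 27). At 0.277 mg/L (14 splits, 1 gene, highest other 9) and 0.878 mg/L (9 splits, 1 gene, highest other 5) chance cannot be excluded for the count. The 1 gene was FMg025031, whose adjusted p over all tested genes was 9.26e-15 and 4.69e-17 at these doses in the fit of all 80 fish. Between the chemicals, chance is unlikely at the highest pair (1 split, 3482 genes, highest other 2) and the next (1 split, 60 genes, highest other 3). At the 3 lowest pairs the real count in these fits was 0 and the 100 splits say nothing (highest others 9, 10 and 58). At 0.277 against 0.268 mg/L (22 splits, 1 gene, highest other 3) chance cannot be excluded for the count. That gene was FMg025031, at 260 to 570.5 CPM with 6PPD-Q and 43.5 to 77.4 with 6PPD, and its difference had an adjusted p of 1.5e-09 in edgeR. For the trends, chance is unlikely for 6PPD (1 split, 2883 genes, highest other 14), 6PPD-Q (1 split, 31 genes, highest other 6) and the difference of slopes (1 split, 1084 genes, highest other 273). Splits that called 87, 119, 58 and 27 genes where the real one called 0 may point to a structure of the fish that the groups do not follow, but what sets these splits apart was not tested.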
